A study of Homo sapiens with 2 samples.

How the data were processed

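Chromatin immunoprecipitation with sequencing (ChIP-seq) was done in U-87 MG cells, an established human glioma line, that overexpressed the beta-1 subunit of soluble guanylate cyclase (sGCβ1). The subunit is encoded by GUCY1B3, whose current symbol is GUCY1B1. Per the labels, 1 ChIP library was made with an antibody against sGCβ1 and 1 input library without antibody. The data used here are the interval list of the ChIP library. The input library had no file used here, and no read or signal from it enters any value.

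Per the series' design text, reads of 75 nt from a NextSeq 500 were aligned to hg19 with BWA at default settings. Per the same text, reads were kept if they passed the sequencer's purity filter, had at most 2 mismatches and aligned at a single place, and intervals were called with MACS. BWA and MACS are also named in the submitters' processing notes; their versions, and whether MACS took the input library as its control, are not given in the sources used here. Nothing was pooled, per the labels. The total number of reads is not given in the sources used here, so the depth behind each interval is unknown.

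Per the file headers, the deposited list gives for each interval its chromosome, start, end, summit, a peak value, an average value, a MACS score, and counts of CpG islands, promoters and genes. The peak value is a signal: the authors' maximum fragment density in the interval, in whole numbers, called height here. The average value is the authors' mean density signal over the interval. The score deposited by the authors is minus 10 times log10 of the MACS p-value, and its lowest value, 70, corresponds to p = 1e-07. The authors' list also names the genes assigned to each interval, with the distance from summit to gene start and whether the summit lies upstream, inside or downstream of the gene. Heights and scores are the authors' own and were used only to describe, rank and filter intervals within this list. The design fixed in advance called for fold enrichment as the strength, with the height as its replacement where no fold column exists; height was used throughout.

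Coordinates are those of the deposited list (hg19). The reference was the GRCh37 primary assembly, which is the same build, with the GENCODE version 44 annotation mapped to GRCh37. An interval was placed by its deposited summit: promoter if within 1000 bp of the start of a protein-coding transcript, otherwise gene body if inside a protein-coding gene, otherwise outside. Shares have exact Clopper-Pearson 95% intervals and chromosome counts exact Poisson 95% intervals; both cover counting error only. Position shares were set beside 1000 random placements of the same intervals on their own chromosomes, avoiding unsequenced bases; alternatives used 200 placements, and 1000 reassignments of height. Sequence classes were set beside 20 placements. Expected counts per chromosome came from chromosome length over the 22 autosomes and X. These lengths included unsequenced bases, so ratios of chromosomes with many such bases are biased low. Differences of median height between positions were ranked among 10000 random reassignments of the positions. The share of intervals with a neighbour within 10000 bp was set beside 1000 uniform placements between the outermost summits of each chromosome. GC content and 6-mers were taken over 200 bp around the summit and set beside 1000 random placements, with both strands counted together; 100 placements were used within each position class.

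A gene carried an interval if the deposited list assigned one to it. Of 3677 symbols in the list, 3405 (92.6%) matched a current gene at that position, through the annotation and older symbols. The 16 gene lists were fixed before the data were examined. For each, the share of members with an interval was ranked among 10000 random lists of the same size, drawn from 20136 protein-coding genes and matched on 10 gene-length classes, with ties split evenly in the percentile. In total 4 list entries had no protein-coding gene in the annotation and were left out. With 1 ChIP library there is no replicate error: no p-value was computed, and percentiles describe this list and are not tests of a condition.

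The genes named were set by a rule written before the data were examined: GUCY1B3, GUCY1A3 and CDKN1A always; the genes assigned to the 10 tallest intervals; the 5 protein-coding genes with most intervals; and for each list up to 3 members whose tallest interval is highest. Ties went by chromosome, then start. Some genes that the rule sets are not described here. Genes named outside the rule are said to be so where they appear, except RPS3A and PPP5C. Those are named only because an interval described for another gene lay at their starts. Alternatives fixed in advance were stronger parts of the list by score or height, autosomes only, merging of intervals within 1000 bp, promoter windows of 500 and 5000 bp, overlap in place of the summit, unmatched random lists, other ways to assign genes, other neighbour distances, an expectation from gene numbers, and whole intervals for composition. A further 6 were added after the data were seen, among them removal of intervals with a tRNA-like sequence or at a gene transcribed by RNA polymerase III. The sequence classes in the closing section were chosen after the data were seen.

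Position shares, list percentiles, neighbour shares, height differences, 6-mer ratios and the exact intervals were tested on simulated data; GC content, sequence classes and the ratios in the closing section were not. With 30% of 4169 intervals placed at gene starts, the promoter share was planted at 32.4% and recovered as 32.2%. A planted list of 200 genes among 20136 reached percentile 100, and 2.5% of 200 random lists fell outside the central 95%. For lists of long genes, 7% fell outside with length matching and 96.5% without it. For pairs of intervals planted close together among 4169, a share of 23.4% was planted and 22.8% recovered. A difference of medians of 5 planted between position classes came back as 6, a departure of 1 beside a reported difference of 2. A 6-mer planted at 3.52 times its background over 4169 sequences came back at 3.57 times. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9 were used.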

Results

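Binding of sGCβ1 to chromatin was profiled by ChIP-seq in U-87 MG glioma cells that overexpressed this subunit. Soluble guanylate cyclase is the nitric oxide receptor that makes cyclic GMP, and sGCβ1 is its haem-binding subunit. The question was where in the genome the antibody against sGCβ1 recovers DNA. The study has 2 samples, 1 ChIP library and 1 input library, and values below come from the intervals that the authors called in the ChIP library. No replicate exists, so no value has a replicate error, and the read total is not given in the sources used here.

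The list held 4169 intervals on hg19. Their median length was 1296 bp, with a range from 468 to 15187 bp. Height, the authors' maximum fragment density in an interval, had a median of 14 and an interquartile range of 12 to 18, and the tallest interval reached 263. The median MACS score was 99.2. A height of 40 or more was reached by 411 intervals (9.86%).

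The 10 tallest intervals all sat at starts of protein-coding genes. At 263, the tallest lay at NCOA5, a nuclear receptor coactivator, on chromosome 20 from 44717402 to 44719526, with its summit at -44 bp from the start (negative is upstream). Next came NEURL4 on chromosome 17 (7231943 to 7234031) with a height of 254 and DRAM2 on chromosome 1 (111681893 to 111684118) with 243, the latter interval shared with CEPT1. The interval at CDK8, the kinase of the Mediator complex, on chromosome 13 (26827387 to 26828776) had a height of 237, and that at LEO1, a subunit of the Paf1 transcription complex, on chromosome 15 (52262995 to 52264681) had 234. The highest MACS score in the list, 3233, was that of LEO1. A score of exactly 3100 was shared by 22 intervals, among them those at NEURL4 and CDK8. Why they share it is not known, so ranks by score near the top are uncertain.

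Others of the 10 tallest intervals were at shared or single starts as well. A height of 213 was found both between ITFG1 and PHKB on chromosome 16 and at C7orf20, now GET4, on chromosome 7, where SUN1 was also assigned. A height of 210 was found at ZMAT2 on chromosome 5, with HARS and HARS2 assigned, and 206 at NARFL, now CIAO3, on chromosome 16. The interval at NEURL4 was also assigned to ACAP1. All 10 summits lay within 1000 bp of a protein-coding transcript start, and 9 of the 10 intervals overlapped a CpG island in the authors' count. The 60 bp around the NCOA5 summit, chromosome 20 from 44718595 to 44718654, read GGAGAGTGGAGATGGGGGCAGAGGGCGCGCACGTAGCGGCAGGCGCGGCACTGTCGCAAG and were 71.7% G and C. Around the DRAM2 summit, chromosome 1 from 111682819 to 111682878, the sequence was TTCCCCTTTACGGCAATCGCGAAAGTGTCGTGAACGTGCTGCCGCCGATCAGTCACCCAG, with 58.3% G and C.

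**Figure D1:**
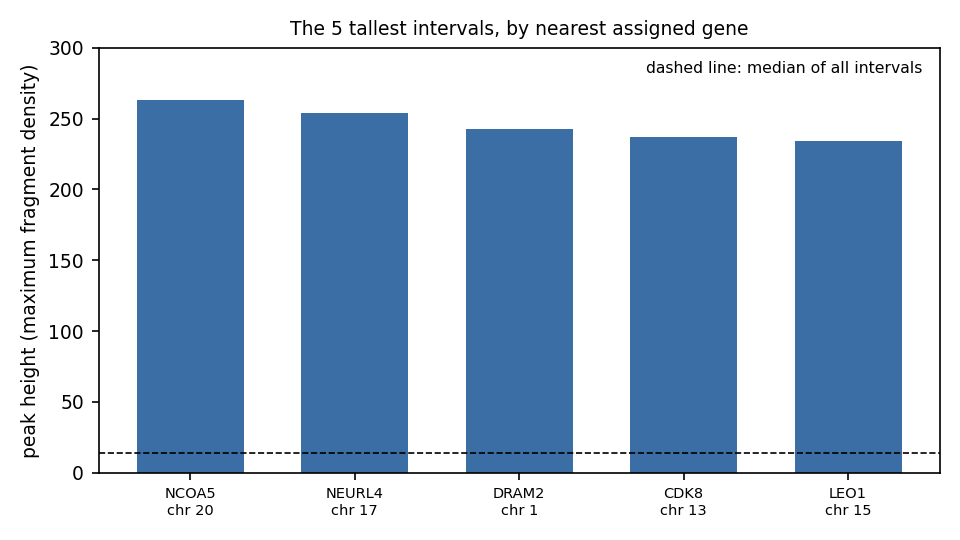
Height of the 5 tallest intervals in the sGCβ1 ChIP library, as the authors' maximum fragment density (vertical axis, from 0), with the nearest assigned gene and its chromosome under each bar; the dashed line is the median of all 4169 intervals. Heights run from 234 at LEO1 to 263 at NCOA5, against a median of 14.

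The gene of the overexpressed subunit itself carried no interval, on a chromosome that held only 38, at 0.145 times the expectation from its length. GUCY1B3 lies on chromosome 4 from 156680144 to 156728963, and the nearest interval was 4659 kb away, at the start of the ribosomal protein gene RPS3A, with a height of 18. GUCY1A3, the gene of the partner subunit alpha-1, on chromosome 4 from 156587878 to 156658211, also had 0 intervals. CDKN1A, a p53 target that halts the cell cycle, had 0 intervals, and the nearest one was 637 kb away.

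Intervals were concentrated at gene starts. Of the 4169 intervals, 1391 (33.4%, 95% interval 31.9 to 34.8) had their summit within 1000 bp of a protein-coding transcript start, 11.6 times the mean of 2.87% over 1000 random placements. Gene bodies held 1275 intervals (30.6%, against 45.3% in random placements), of which 1178 were in introns and 97 in exons. A further 1503 (36.1%, against 51.8%) lay outside protein-coding genes. Promoter intervals overlapped a CpG island in 88.6% of cases, compared with 5.96% in gene bodies and 10.0% outside genes. No random placement reached the promoter share, its maximum being 3.86%. The fold over random placements depended on the definition of a promoter and was 18.97 for a window of 500 bp, 3.70 for 5000 bp, 7.74 for any overlap and 5.06 with the starts of all annotated transcripts.

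**Figure D2:**
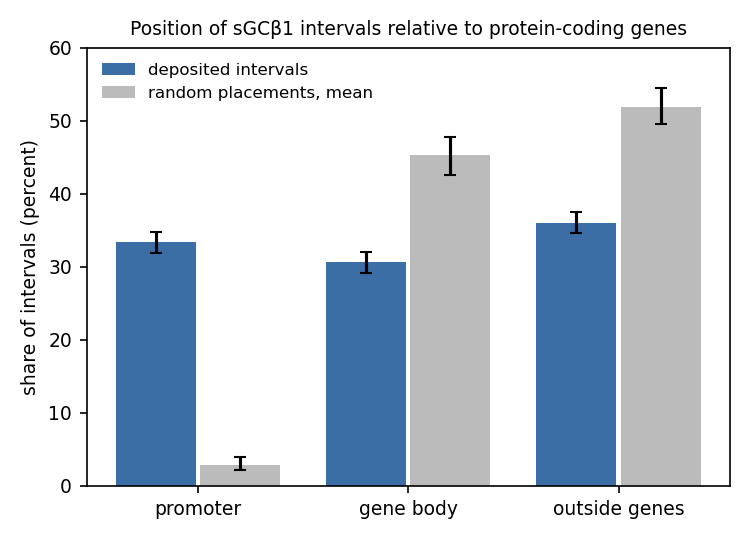
Share of intervals (percent, from 0) in promoters, gene bodies and outside protein-coding genes for the deposited intervals and for 1000 random placements. Blue bars have exact 95% intervals from counting error, and grey bars are means with the lowest and highest placement; promoters held 33.4% of intervals and 2.87% of random placements.

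In the full list, promoter intervals were also the taller ones by median. Median height was 16 at promoters and 14 in gene bodies and outside genes. The difference of 2 lay at percentile 100 of 10000 reassignments against either class, where chance gave differences between -1 and 1. Tall intervals, with a height of 40 or more, were frequent at promoters (199 of 1391, 14.3%) and outside genes (190 of 1503, 12.6%) and rare in gene bodies (22 of 1275, 1.73%). Medians of gene bodies and of intervals outside genes differed by 0. Among intervals at or above the upper quartile of score, the difference of gene bodies to intervals outside genes was -15, that of promoters to the latter was 3, at percentile 85.7, and that of promoters to gene bodies was 18. Without tRNA-like and polymerase III gene intervals promoters exceeded either class by 1, and at or above the median height they exceeded intervals outside genes by 1.

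Chromosomes 4 and X held far fewer intervals than their length would give. Chromosome 4 had 38 intervals, 0.145 times its expectation (95% Poisson interval 0.102 to 0.199), and X had 25, 0.117 times (0.0759 to 0.173). Chromosomes 20 and 19 stood at the other end, with 177 and 164 intervals, 2.05 times (1.76 to 2.37) and 2.02 times (1.72 to 2.35) the expectation. Chromosome 7, with 363 intervals, stood at 1.66 times (1.495 to 1.84). Of 23 chromosomes, 9 had an interval wholly above 1 and 8 wholly below. Lengths included unsequenced bases, so these counts could change if such bases were left out. Against an expectation from protein-coding gene numbers, chromosome 4 remained low at 0.241 and X at 0.139, chromosome 7 stood at 1.88 and 20 at 1.57, while the gene-rich chromosome 19 fell below 1, at 0.534. Other chromosomes whose direction turned are given in the closing section. DNA copy number, which is abnormal in this line, was not separated from binding.

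**Figure D3:**
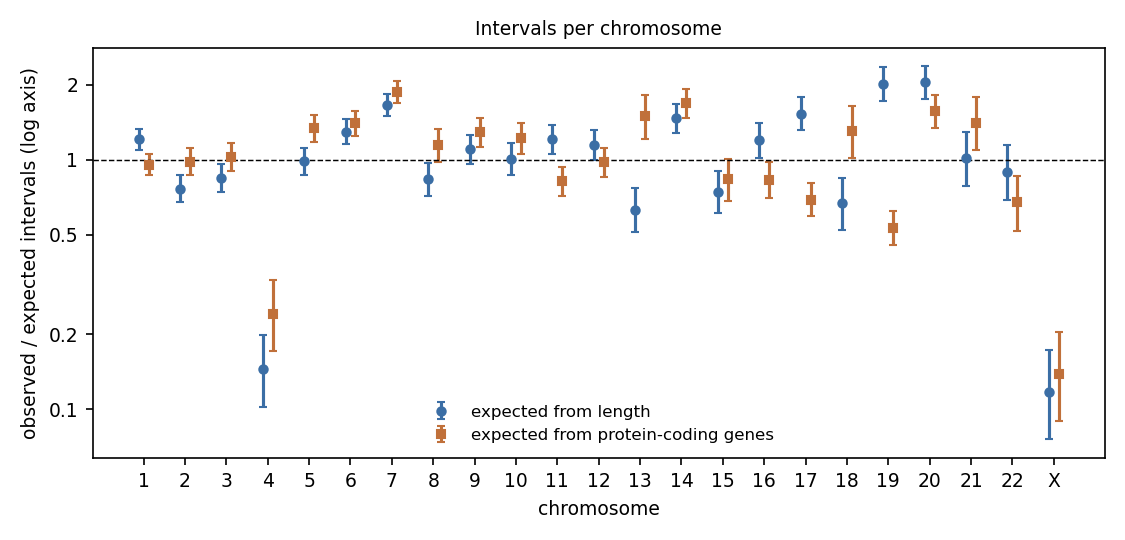
Observed over expected intervals (log axis) for the 22 autosomes and X, with the expectation from chromosome length (circles) or from the number of protein-coding genes (squares) and exact Poisson 95% intervals; the dashed line marks 1. Chromosomes 4 and X lie far below 1 on both scales, at 0.145 and 0.117 by length.

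Genes of the translation and chromatin machinery carried intervals more often than genes of like length. For this and every other list, random lists were matched on gene length only. CpG islands at gene starts and gene expression were not controlled, so an excess need not reflect the function of the genes. Of 83 cytosolic ribosomal protein genes, 32 (38.6%) had an interval, against a mean of 11.5% in random lists, with RPS16 (height 146, summit at -38 bp), RPS29 (75, at -506 bp) and RPL10 (83, with the summit 13189 bp away, nearer another gene's start) the tallest. Of 70 canonical histone genes, 33 (47.1%, against 9.21%) had an interval, but neighbouring histone genes shared intervals, and the tallest intervals of these 33 genes were 14 distinct ones. Random lists draw genes singly and do not keep neighbours together, so the percentile does not account for this sharing. The median height of their tallest intervals was 13. The tallest intervals assigned to histone genes lay away from the genes themselves: a height of 96 was found 11076 bp from the start of HIST1H2AH, and HIST1H2AM and HIST1H2BO shared one of 65 outside any protein-coding gene. Among 37 immediate early and housekeeping genes, 16 (43.2%, against 12.3%) had an interval, among them FOSB (69, at 10656 bp, at another start) and the transcription factor FOS (61, at -137 bp). These 3 lists lay at percentile 100.

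Lists of nuclear regulators and of progenitor factors also stood above random lists. Of 68 chromatin modifiers, 23 (33.8%, against 18.1%, percentile 99.92) had an interval, led by EED of Polycomb complex 2 with 118, the acetyltransferase KAT5 with 107 and the deacetylase HDAC2 with 51, each within 1000 bp of the gene start. Of 41 glioma stem cell and neural progenitor factors, 14 (34.1%, against 14.0%, percentile 99.95) had one. ZEB1, a zinc finger repressor, led with a height of 76 at its start, followed by SALL2 (49, at 25769 bp) and FOSL1 (24, at 9373 bp), both at other genes' starts. Of 56 DNA damage repair genes, 16 (28.6%, against 17.1%, percentile 98.5) had an interval, with RAD52 at 175, PARP2 at 59 and APEX1 at 49, all at their starts. Of 54 cell cycle regulators, 14 (25.9%, against 15.2%, percentile 98.0) had one, with CDK4 at 76 and CHEK1 at 49 at their starts and CDC25C at 32, at -6244 bp and another gene's start.

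Cancer driver lists also had more genes with an interval than the mean of random lists. Of 37 p53 pathway genes, 11 (29.7%, against 14.4%, percentile 99.0) had an interval, among them MDM4 with 104, but at -9682 bp, and POLH with 27, but at 54202 bp, at another gene's start. Only 4 of the 37 had one within 1000 bp of a start, at percentile 73.9. Of 39 glioblastoma driver genes, 12 (30.8%, against 17.7%, percentile 97.7) had one, led by MDM4 and CDK4 with the heights given. For glioblastoma and cell cycle genes the share equalled the upper bound of the central 95%, and only the percentile, which splits ties evenly, places them above it. The calls for p53, cell cycle, glioblastoma and repair genes were lost in several stronger parts of the list or with other assignments, with percentiles down to 50.7 for the p53 list. That for chromatin modifiers was lost with intervals inside gene bodies only, at percentile 92.6.

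In 5 lists the percentile lay within the central 95% of random lists. For NO-cGMP signalling it was 6 of 46 genes (13.0%, against 17.8%, percentile 20.8). Among them were PRKG1, the cyclic GMP-dependent protein kinase, with a height of 23 at its tallest, NOS1 with 14, and NPR1 with 102 but at -7452 bp, at another gene's start. No gene of this list had an interval within 1000 bp of its start (0 of 46, against 8.56%, percentile 0.815). Random lists were not matched on chromosome, and members such as GUCY1B3 and GUCY1A3 lie on chromosome 4, which held few intervals. For kinetochore and mitotic chromosome genes it was 13 of 56 (23.2%, percentile 92.6), with AURKB (119, at -12325 bp), KNL1 (105, listed as CASC5) and CENPN (38). For mesenchymal, matrix and adhesion genes it was 11 of 45 (24.4%, percentile 89.8), with COL6A1 (16, at -7743 bp), LAMA4 (16, in an intron) and VIM (15, at its start). For angiogenesis and hypoxia it was 9 of 38 (23.7%, percentile 88.6), with HIF3A (193, an interval at the start of PPP5C, 49999 bp from the start of HIF3A), ARNT (17) and DDIT4 (16). For large genes of common fragile sites it was 7 of 29 (24.1%, percentile 60.1), among them RBFOX1 (17) and DAB1 (14).

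Zinc finger and olfactory receptor genes carried few intervals. Of 508 ZNF genes, 43 (8.46%, against 15.6%) had one, and of 399 olfactory receptor genes, which are silent in most tissues, 5 (1.25%, against 10.3%), both at percentile 0. Random lists were not matched on chromosome and did not keep neighbours together, so these percentiles do not account for members that lie close together. Among intervals at or above the upper quartile of score, the ZNF list was no longer outside the central 95%, at percentile 17.1. In the full set the tallest of these genes were ZNF839 (150, at -2640 bp), ZNF862 (137), ZNF213 (99, 15647 bp away), OR6S1 (100, 10554 bp away), OR2B2 (65, 9902 bp away) and OR2V2 (18, 9417 bp away). Of all 20136 protein-coding genes, 3099 (15.4%) had an interval.

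**Figure D4:**
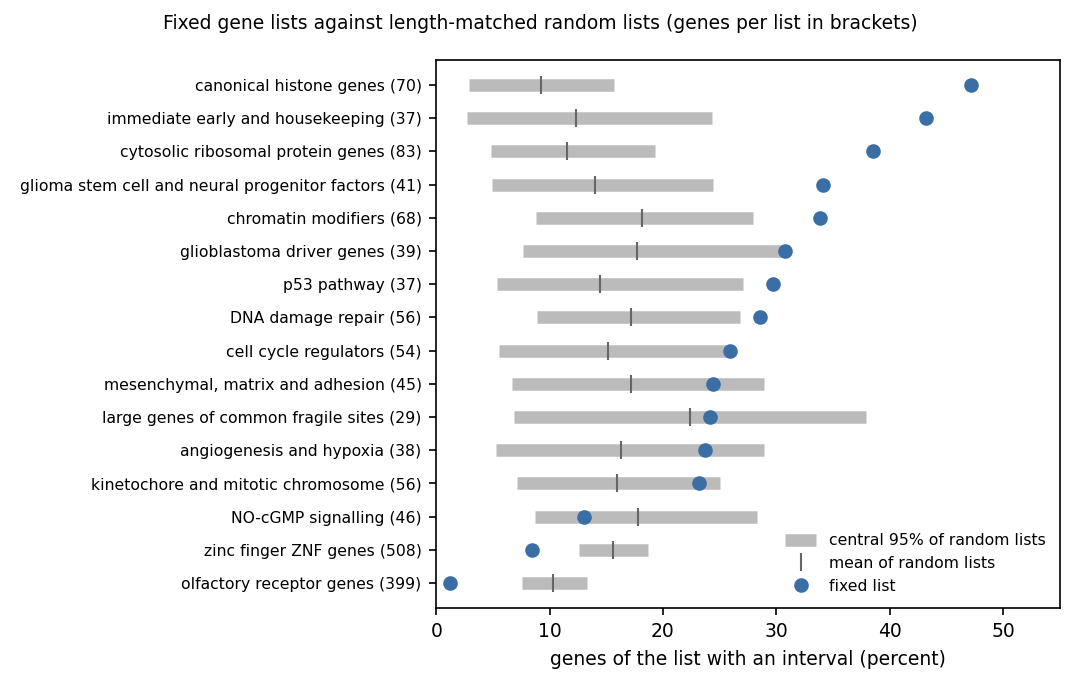
Share of genes with an interval (horizontal axis, percent) in each of the 16 lists fixed in advance (points, number of genes in brackets), with the mean (tick) and the central 95% (grey bar) of 10000 length-matched random lists. Canonical histone genes stand highest at 47.1% and olfactory receptor genes lowest at 1.25%.

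Some genes held several intervals. PRKG1 on chromosome 10 had 15, with heights from 10 to 23, over a gene of 1307536 bp. MKLN1 had 9, HMGA2 and PALM2AKAP2 had 8 each, and NAV2 had 7. Relative to length, HMGA2, an architectural chromatin protein gene of 141832 bp, was densest of these 5, with 5.64 intervals per 100000 bp. In total 120 protein-coding genes had 3 or more intervals. Across the genome 642 intervals (15.4%, 95% interval 14.3 to 16.5) had a neighbour within 10000 bp, against a mean of 3.41% and a maximum of 4.61% in random placements. At 1000 bp the share was 0.288%, inside the range of random placements (mean 0.346%), and at 100000 bp it was 56.3%, against 28.9%. Called intervals are separate regions with a median length of 1296 bp, so their summits can rarely lie within 1000 bp. Random placements are points without that limit, so the value at 1000 bp does not speak to clustering at short range.

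Sequence around the summits was rich in G and C. Median GC content over 200 bp was 50%, against 40.6% in random placements, and it was 62.5% at promoters, 45.5% in gene bodies and 47.0% outside genes. The 6-mer most raised over random placements was CGCGAC, at 18.8 times. Among promoter intervals alone, CGTCGC led with 47.8 times, against placements that were not limited to promoters or CpG islands. Over all intervals and against windows 600 bp from the same summits, CGTCGC was raised 2.77 times. In gene bodies CGACCG and GAGTCA stood highest, both at 3.65 times with counts of 11 and 410, and GACTCA was at 3.51 times. Outside genes CGAACC led, at 11.6 times. Over all intervals and against windows 600 bp from the same summits, other words led, CGTGAC at 3.97 times, ACGTGA at 3.65 and CACGTG at 3.38, while CGCGAC was raised 2.5 times, GAGTCA 2.34 times and CGAACC 2.95 times.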

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

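The 6 alternatives added after the data were seen were mean density as the strength, MACS score as the strength, starts of all annotated transcripts, flanks as background for 6-mers, flanks as background for sequence classes, and removal of intervals with a tRNA-like sequence or at a listed polymerase III gene. All others were fixed before the data were examined. The planned use of height as the strength equals the reported values, as no fold column exists, and gave no separate value. No paired analysis was possible, with 1 ChIP library. Read depth is unknown, so what a deeper library would add could not be assessed.

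Of the chromosome ratios whose 95% interval excludes 1 by length, 9 crossed 1 with the expectation taken from gene numbers. They were chromosome 19 at 0.534, 1 at 0.956 (0.866 to 1.05), 3 at 1.03, 8 at 1.14, 11 at 0.823, 13 at 1.497, 16 at 0.834, 17 at 0.693 and 18 at 1.30; the new intervals of 1, 3 and 8 span 1. Ratios whose interval spans 1 by length crossed it too, among them chromosome 5 at 1.34 and 12 at 0.978 by gene numbers and 21 at 0.484 (0.209 to 0.954) in the upper quartile of score. The change by gene numbers follows from the number of genes per length. By gene numbers chromosome 4 stood at 0.241, 7 at 1.88 and 20 at 1.57. At or above the median height, 7 stood at 1.89 and 20 at 2.77; the cause was not tested.

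There were 2085 intervals at or above the median score, 1043 at or above its upper quartile and 2537 at or above the median height, where ties were kept. In these 3 parts, in that order, the promoter fold over random placements was 13.0, 14.2 and 13.3 and the gene body fold 0.566, 0.421 and 0.567. Outside genes the fold was 0.754 in the upper quartile. The promoter fold was 18.97 with a 500 bp window, 3.70 with 5000 bp, 7.74 with any overlap and 5.06 with all transcript starts. All transcript starts also gave 0.640 for gene bodies and 0.629 outside genes, and the 5000 bp window 0.625 for gene bodies. Without tRNA-like and polymerase III gene intervals the fold outside genes was 0.658.

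In the upper quartile of score the difference in median height of promoters to intervals outside genes was 3, at percentile 85.7. That of gene bodies to intervals outside genes, 0 in the full list, was -15 in the upper quartile of score, -1 at or above the median height, -0.246 by mean density and -7.51 by MACS score.

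Against 11 lists with a percentile outside the central 95% of random lists, 2 of them with a share equal to the upper bound, there were 7 at or above the median height and 6 with intervals inside gene bodies. The p53 percentile was 50.7 (median score), 81.0 (upper quartile), 94.4 (median height), 73.9 (starts only) and 53.6 (gene bodies). Glioblastoma drivers had 86.6, 78.4, 76.6, 97.03 and 88.1 in the same order. Cell cycle had 90.9 (upper quartile), 95.3 (median height) and 93.3 (gene bodies). Repair had 93.7 (median score), 96.1 (median height), 97.4 (without tRNA-like), 89.99 (starts only) and 94.5 (gene bodies). Chromatin modifiers had 92.6 with gene bodies, and ZNF genes 17.1 in the upper quartile. Among lists inside the range, NO-cGMP signalling moved to 0.815 with starts only and kinetochore genes to 99.6 in the upper quartile. The cause was not tested.

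The share with a neighbour was 13.1% at or above the median score, 13.9% at or above the median height, 11.5% after merging, 13.0% without tRNA-like intervals, 0.288% at 1000 bp and 56.3% at 100000 bp. Over whole intervals and against flanks, CGCGAC stood at 11.1 and 2.5 times, GAGTCA at 1.85 and 2.34, and CGAACC at 4.08 and 2.95.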

Other observations

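The sequence classes and small RNA genes were chosen after the data were seen, as were the tests of tRNA-like intervals outside the chromosome 6 region and of histone starts inside it. The classes hold 6-mers that led or stood high in the comparisons above, such as CACGTG and GAGTCA. Their excess over flanks and random placements was therefore favoured by the choice and is no separate support. Most of the listed genes transcribed by RNA polymerase III carried an interval well above the median height. Of 18 such small RNA genes found in the annotation, 16 had an interval, with heights from 37 to 193: VTRNA1-3, a vault RNA, reached 193, RMRP, the RNA of RNase MRP, 180, RN7SL2, an RNA of the signal recognition particle, 99, RNY1, a Y RNA, 90, and RN7SK 79. RNU6-7 and RNU6-8 had none. RPPH1 and RN7SL1 were listed but not found in the annotation, so an interval at either was not recognised as a polymerase III gene interval. Whether any interval assigned above to another gene lies at them was not examined. Of 4 annotated small RNA genes transcribed by polymerase II, RNU4-1 and RNU5A-1 had heights of 13 and 12, and RNU1-1 and SNORD118 had no interval. A tRNA-like pair of internal promoter boxes (A box and B box) lay within 150 bp of the summit in 216 intervals (5.18%, 95% interval 4.53 to 5.90), against 0.612% of flanks and 0.379% of random placements. Their median height was 65, against 14 for all others, and they made up 163 of the 411 intervals of height 40 or more. On chromosome 6, the stretch from 26031568 to 28950624 held 116 intervals, of which 75 were tRNA-like. Without tRNA-like and polymerase III gene intervals the chromosome 6 ratio was 1.02, against 1.30 with them. With them it was 1.83 at or above the median score and 2.55 (2.16 to 2.997) at or above its upper quartile, the highest of the chromosomes there.

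Promoters carried a pair of other sequences. The E-box CACGTGAC lay within 100 bp of the summit in 124 of 1391 promoter intervals (8.91%, against 0.503% of flanks), with a median height of 28.5. The 8-mer GCCGTAAA lay near 49 promoter summits (3.52%, against 0.216% of flanks), with a median height of 91. It was near the summit in 6 of the 10 tallest intervals, among them NCOA5, NEURL4, DRAM2, LEO1 and ZMAT2. The AP-1 site TGASTCA (S is C or G) showed the opposite distribution: 20.8% of gene body intervals and 20.8% of those outside genes had it within 100 bp, against 4.82% and 5.46% of flanks, while promoters had it in 2.95%, against 2.77% of flanks. AP-1 sites were rare among tall intervals, in 4 of 411 (0.973%) against 615 of 3758 shorter ones (16.4%). In total 260 of the 411 tall intervals (63.3%) had at least 1 of these 4 sequence classes or lay at a polymerase III gene, against 775 of the 3758 shorter ones (20.6%).

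Tall tRNA-like intervals were weighed against technical explanations. Reads shared between gene copies would need repeated sequence, and 1.09% of 75-nt windows near these summits occur more than once exactly in the genome. Reads were kept only if they aligned at a single place, and near-copies with mismatches were not counted. Whether reads were shared between near-copies is therefore not decided. Intervals at ribosomal protein and histone gene starts stood at 0.2 times the tRNA-like median (95% interval 0.183 to 0.250). As a set, intervals at these polymerase II gene starts were thus not recovered to the same height. Single polymerase II starts exceeded the tRNA-like median, among them RPS16 at 146 and NCOA5 at 263. The comparison therefore does not cover polymerase II genes in general. It cannot decide whether heavy transcription by polymerase III itself gives tall intervals, since no such gene is in the comparison. Within the chromosome 6 region, other intervals were 0.883 times as tall (0.719 to 1.07), which leaves its state open there. Heights in the region were not uniform, however. The 11 intervals at histone starts had a median of 13, 0.217 times the tRNA-like median of 60. Extra copies of the whole region would raise these starts too, so they cannot account for this difference in height within the region. The ratio would be the same with or without extra copies, so whether the region has them is not decided. Outside the region, tRNA-like intervals were 4.93 times as tall as others. Contact of sGCβ1 or of the antibody with polymerase III genes may be a hypothesis for the rest, which signal from input or a control antibody in the same cells would be needed to test; no biological explanation was tested.

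AP-1 sites outside promoters were weighed likewise. If base composition were the source, sites would be spread evenly, but their density within 50 bp of the summit was 3.56 times (2.99 to 4.25) that at 400 to 500 bp. The site holds GAGTCA, which stood high in the same summit windows, and that choice favours a high ratio. If a few long regions were the source, thinning to 1 interval per 100000 bp would remove the excess, but 21.8% (19.9 to 23.7) of 1905 such intervals had a site, against at most 4.15% in 20 random placements. That these intervals mark open or enhancer-like chromatin, recovered with or without sGCβ1, may be a hypothesis; the signal of the input library was not analysed here, so this stays open and no biological explanation was tested.

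Few intervals on chromosome 4 were weighed against gene density and copy number. Low gene density is argued against by the ratio to gene numbers, 0.241 (0.171 to 0.331). A lower copy number would be expected to lose weak intervals more than strong ones; 16 intervals lay at or above the median score and 22 below it, and the ratio of their observed over expected values was 0.727 (0.382 to 1.38), and with counts this small the explanation cannot be told apart from an even loss. Alignment and filtering by the authors were not tested, and no biological explanation was tested.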
